A study of Mus musculus with 6 samples.

How the data were processed

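Total RNA from 6 mouse samples was labelled with biotin and measured on 1 oligonucleotide expression array each, per the labels. The samples were 2 preparations of bone marrow-derived dendritic cells (BMDC), 2 of follicular dendritic cells (FDC) grown in culture, 1 of FL-Y, a line with FDC-like features that carries the SV40 transforming genes, and 1 of FL-Y after an antibody to the lymphotoxin beta receptor had activated it. Nothing in the labels says that the paired arrays came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

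The deposited table holds 1 intensity value per probe set and array, on a linear scale, for 45101 probe sets, of which 64 are control probe sets. The mean of each array after trimming 2% at each end was 500 in the deposited values, so each array had been scaled to a common target before deposit. The program that computed these values, its version and its background handling are not given in the sources used here. No detection call was used. The number of arrays limits the precision. The 20th percentile of the arrays lay between 8.7 and 15.4 signal units and was used here as a mark of background level. It is a cut of these values and not a measured limit of detection, so signals above it can also be background.

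Gene symbols came from the platform annotation: 34945 probe sets had 1 gene, 932 had several and 9211 were not listed there and stay unnamed here. No gene was named from a probe set with several or from a control probe set. Of the annotated probe sets, 34754 had a gene identifier in a reference gene table (assembly GRCm38.p6, used for names only), and 0 symbols needed an update. The result covered 18193 named genes, 12750 of them tested. A gene was represented by its probe set with the highest mean log2 value over the 6 arrays.

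Values were analysed as log2(signal + 14.2), the offset being the median over the 6 arrays of each array's 20th percentile. The offset understates the change of dim genes, and every fold and log2 difference here is on that scale. The arrays were used as scaled by the authors, because their trimmed means differed by less than 5%. A probe set was tested if its mean over the 4 FDC and BMDC arrays lay above the 40th percentile, equal to a signal of 46.4, which left 27022 probe sets. FDC and BMDC were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual and 3.35 prior degrees of freedom), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. All tests were two-sided. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so no single gene was tested that way.

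The 27 gene lists, the comparisons, the tests, the rule for named genes and the alternative settings below, except the technical batch, were fixed before the data were examined. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and does not compare it with other genes. The FL-Y arrays have no replicate, so their differences were described without a test: a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The genes named are the 10 largest rises and the 10 largest falls past the threshold, up to 4 called members of each list (the 2 with the largest difference where none was called), 10 genes fixed in advance, and for activation of FL-Y the 10 largest differences in each direction with the 6 largest of the lymphotoxin list. Other genes that are named were chosen after their values were seen, and this is said where they appear.

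The test was checked on simulated data for 27022 probe sets, 200 of them changed in each of 10 simulations. It recovered 0.448% of changes of 1 on the log2 scale, 6.72% of changes of 2 and 94.2% of changes of 4, and 8.84% of its calls were false. With 2413 probe sets changed by 4, it recovered 99.3%, and 4.96% of its calls were false. The simulated noise was normal and independent between probe sets, with no shared batch. These rates therefore need not hold for the arrays themselves.

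Batches were sought in the control probe sets. The ratio of the labelling controls to the hybridisation controls was 0.111 on BMDC array 1 and 0.127 on FDC array 1, against 0.527 on BMDC array 2 and 0.332 on FDC array 2. The ratio was 0.0628 on the FL-Y array and 0.0723 on the activated FL-Y array. The first and the second arrays of FDC and BMDC were therefore also treated as 2 technical batches, an alternative chosen after seeing the data. The differences between array 1 and array 2 correlated between the cell types at r = 0.199 across probe sets, which are not independent replicates.

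The other settings tried were no offset with a floor at the 5th percentile (a signal of 3.1), an offset at the 40th percentile (52.3), quantile normalization, rescaling to one median, no filter, a filter at the 60th percentile, eBayes with trend and robust settings, the FL-Y arrays as another group, averaged probe sets of a gene, a threshold of 0.01 and leaving out each array in turn. Another 8 gene lists were written after the deposited values were first seen and before these genes were read. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.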

Results

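Gene expression was measured in cultured FDC (2 arrays), in BMDC (2 arrays), in the FDC-like line FL-Y (1 array) and in FL-Y activated through the lymphotoxin beta receptor (1 array). FDC are stromal cells of the B cell follicle that hold antigen for B cells, and BMDC are antigen-presenting cells grown from bone marrow. The median signal was 76.4 and 84.4 on the BMDC arrays, 82.5 and 79.6 on the FDC arrays, 61.1 on the FL-Y array and 47.9 on the activated FL-Y array. Log2 values correlated across probe sets at r = 0.925 between the BMDC arrays and 0.899 between the FDC arrays, and probe sets are not independent replicates.

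The design names the comparison of FDC with BMDC. Cultured FDC expressed genes of the extracellular matrix at high level, while BMDC expressed genes of myeloid cells and of antigen presentation. Mfap5, a protein of elastic microfibrils, had a mean signal of 38812 ± 9243 (SD, n = 2) on the FDC arrays and 14.4 ± 11.8 (SD, n = 2) on the BMDC arrays, a log2 difference of 10.45 ± 0.47 (SE). The matrix glycoprotein Sparc was higher by 10.17 ± 0.70 (SE). S100a9, a calcium-binding protein of myeloid cells, was at 8.95 ± 8.98 (SD, n = 2) in FDC and 48102 ± 22253 (SD, n = 2) in BMDC, a log2 difference of -11.00 ± 0.53 (SE). The lower signals of these 3 genes reached background level, so the sizes of their differences depend on the offset. Of 27022 probe sets tested, 2413 passed an adjusted p of 0.05 with limma, 1307 higher and 1106 lower in FDC. All 2413 differed by at least 1 on the log2 scale and 2317 by at least 2, the smallest by 1.74. Read by the representative probe set of each gene, 748 genes rose and 688 fell.

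The other largest rises were those of Dcn (9.67), Ccn2 (9.60), Rarres2 (9.40), Pcolce (9.37), Col3a1 (9.14), Tagln (8.98), Iigp1 (8.89) and Col1a1 (8.88), on the log2 scale. Dcn is a matrix proteoglycan, Pcolce helps to process procollagen, Tagln is an actin-binding protein of smooth muscle, and Iigp1 is an interferon-inducible GTPase. The other largest falls were those of Retnla (-10.07), Klk1b11 (-9.30), Mgl2 (-8.99), Clec4n (-8.89), Clec4a2 (-8.86), Cybb (-8.38), F10 (-8.32), Dcstamp (-8.24) and Acod1 (-8.21). Mgl2, Clec4n and Clec4a2 are C-type lectins of myeloid cells, and Cybb is a subunit of the phagocyte oxidase. Including Mfap5, Sparc and S100a9 from above, the lower cell type was under its array's 20th percentile on both arrays for Retnla, Klk1b11, Clec4a2 and Dcstamp, and on 1 of 2 for Mfap5, Sparc, Dcn, Ccn2, Pcolce, S100a9, Mgl2 and Acod1, so the size and rank of these 12 differences depend on the offset. The same holds for the size of some list genes given below: C2, Cxcl9, Cd8b1, Tlr7 and Vwf on both arrays, and Serping1, Fgf7, Cdh11, Ccr2, Hcls1, Fcrls, Ly86, Tlr8, Pecam1, Cd3d and Cd3g on 1 of 2. The adjusted p of the 20 genes with the largest differences ranged from 0.00264 to 0.0107.

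**Figure D1:**
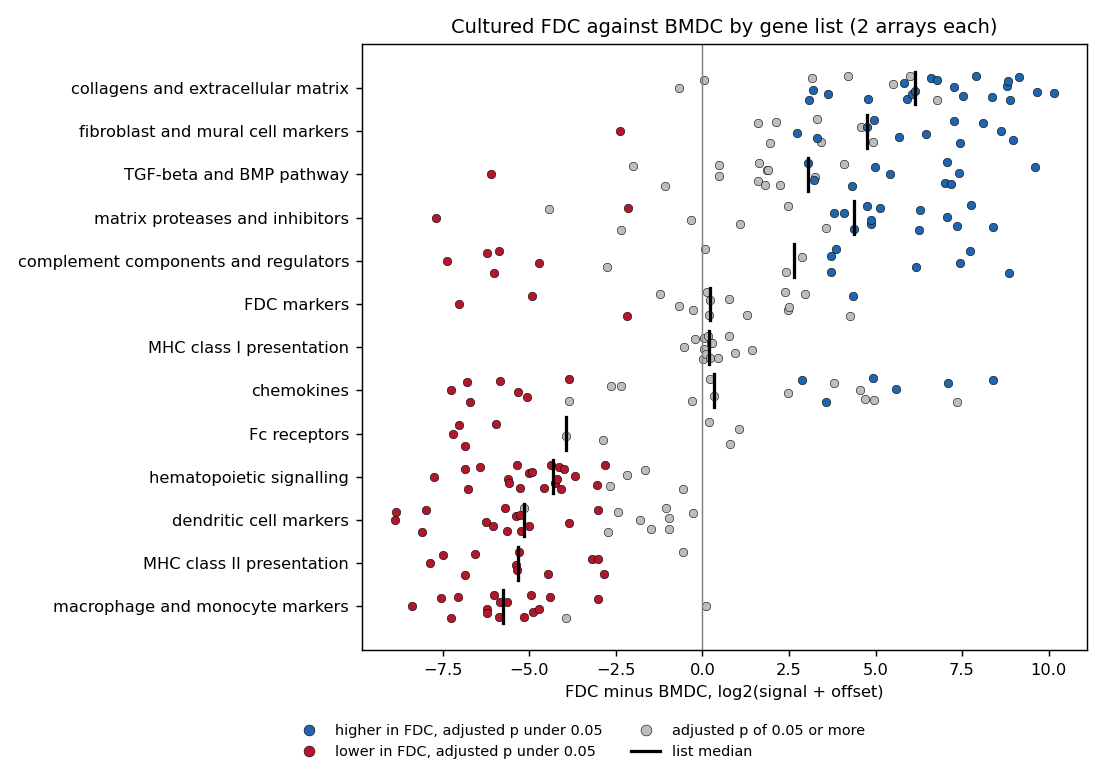
Each point is 1 tested gene, placed by its FDC minus BMDC difference on the log2(signal + 14.2) scale for 13 of the 27 gene lists, with the list median as a black bar and colours for calls at an adjusted p under 0.05. The median lies at 6.14 for collagens and extracellular matrix and at -5.75 for macrophage and monocyte markers.

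Stromal gene lists stood higher in FDC. Of 27 tested genes for collagens and extracellular matrix, 20 rose and 0 fell (25 and 0 adjusted over the list alone; 25 and 0 at an unadjusted p under 0.05), with a median of 6.97 between the first arrays and 5.86 between the second, beside 6.14 for all 4. The camera test placed the list higher (adjusted p = 9.12e-17), but the adjusted p = 0.131 with an estimated correlation. Of 19 fibroblast and mural cell markers, 11 rose and 1 fell (18 and 1 adjusted over the list alone), with Fbln2 higher by 8.61 ± 0.46 (SE), Loxl1 by 8.10 ± 0.46 and Prrx1, a transcription factor of mesenchymal cells, by 7.44 ± 0.43. The list had a median of 4.76 (4.97 and 5.04 within the array pairs) and an adjusted p of 4.30e-11, and adjusted p = 0.127 with an estimated correlation. Among 21 matrix proteases and inhibitors, 13 rose and 2 fell (14 and 4 adjusted over the list alone): the collagen crosslinker Lox rose by 8.38 ± 0.50, Serpinf1 by 7.75 ± 0.60 and Mmp3 by 7.34 ± 0.43, while the macrophage elastase Mmp12 fell by 7.70 ± 0.81 (SE). The list had a median of 4.37 (5.23 and 4.08 within the pairs) and an adjusted p of 3.86e-06, and adjusted p = 0.130 with an estimated correlation. In the TGF-beta and BMP pathway 10 of 23 genes rose and 1 fell (16 and 2 adjusted over the list alone), among them Ltbp2 (7.40), Grem1 (7.17) and Tgfbr3 (7.05). Its median was 3.05 (2.84 and 2.13 within the pairs) and its adjusted p 6.34e-07, and adjusted p = 0.130 with an estimated correlation.

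Gene lists of hematopoietic cells stood lower in FDC. Of 12 tested genes of MHC class II presentation 11 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -5.34 (-4.84 and -5.51 within the array pairs). H2-Aa, a class II chain, was at 185 ± 64.6 (SD, n = 2) in FDC and 46126 ± 8083 (SD, n = 2) in BMDC, and the invariant chain Cd74 was at 449 ± 132 and 43578 ± 3331. The class II list was placed lower (adjusted p = 4.30e-11, and adjusted p = 0.127 with an estimated correlation). Of 23 dendritic cell markers 14 fell and 0 rose (18 and 0 adjusted over the list alone), including Itgax, the CD11c integrin, by a log2 difference of -8.10 ± 0.71 (SE) and the lectin Clec7a at -7.98 ± 0.53. The dendritic cell list had a median of -5.15 (-4.60 and -4.92 within the pairs) and an adjusted p of 7.47e-14, and adjusted p = 0.127 with an estimated correlation. Of 18 macrophage and monocyte markers 16 fell and 0 rose (17 and 0 adjusted over the list alone), with Ccr2 at -7.54 ± 0.74, Csf1r at -7.26 ± 0.43 and Itgam at -7.07 ± 0.40, and the list had a median of -5.75 (-6.35 and -5.08 within the pairs), an adjusted p of 4.69e-13 and adjusted p = 0.128 with an estimated correlation. Of 24 hematopoietic signalling genes 20 fell and 0 rose (23 and 0 adjusted over the list alone), with Tyrobp at -7.74, Hcls1 at -6.85 and Ptpn6 at -6.76. That list had a median of -4.32 (-4.24 and -4.63 within the pairs) and an adjusted p of 3.39e-18, and adjusted p = 0.127 with an estimated correlation. Ptprc, the leukocyte antigen CD45, fell by 4.09 ± 0.53 (SE), and its signals of 823 and 423 on the FDC arrays stood above 12.8 on the FL-Y array.

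Of 17 tested FDC markers 1 rose and 3 fell (5 and 3 adjusted over the list alone), and the list had an adjusted p of 0.608; its median (0.23) and mean (0.31) were positive while fry gave the direction down (adjusted p = 0.269), and its median was 0.87 and -0.09 within the array pairs. Il6 rose by 4.35 ± 0.78 (SE). The Fc receptor Fcgr2b was at -7.03 ± 0.39, Clu at -4.92 ± 0.61 and Mfge8, which binds apoptotic cells, at -2.18 ± 0.38. The complement receptor Cr2 had a log2 difference of -0.68 ± 0.95 (adjusted p = 0.731), and its signals on the FDC arrays were 120 and 4.1. Cxcl13, the chemokine that draws B cells into follicles, had signals of 1288 and 64.5 on the FDC arrays and a difference of 2.48 ± 1.29 (adjusted p = 0.331), which passed the threshold without FDC array 2 (4.50, adjusted p = 0.0144). Vcam1 had a difference of 4.27 ± 0.95 (adjusted p = 0.0566), with 1 of its 3 probe sets called higher, and passed the threshold without BMDC array 2 (5.69, adjusted p = 0.0130). Madcam1 had a difference of 0.13 ± 0.40 (adjusted p = 0.886), Icam1 of -0.26 ± 0.48 (adjusted p = 0.800) and the lymphotoxin beta receptor Ltbr of 0.77 ± 0.57 (adjusted p = 0.493). Without 1 array, Mfge8 lost its call in each of the 4 cases and Il6 lost it without BMDC array 2 (adjusted p = 0.0707) or FDC array 2 (adjusted p = 0.0816).

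**Figure D2:**
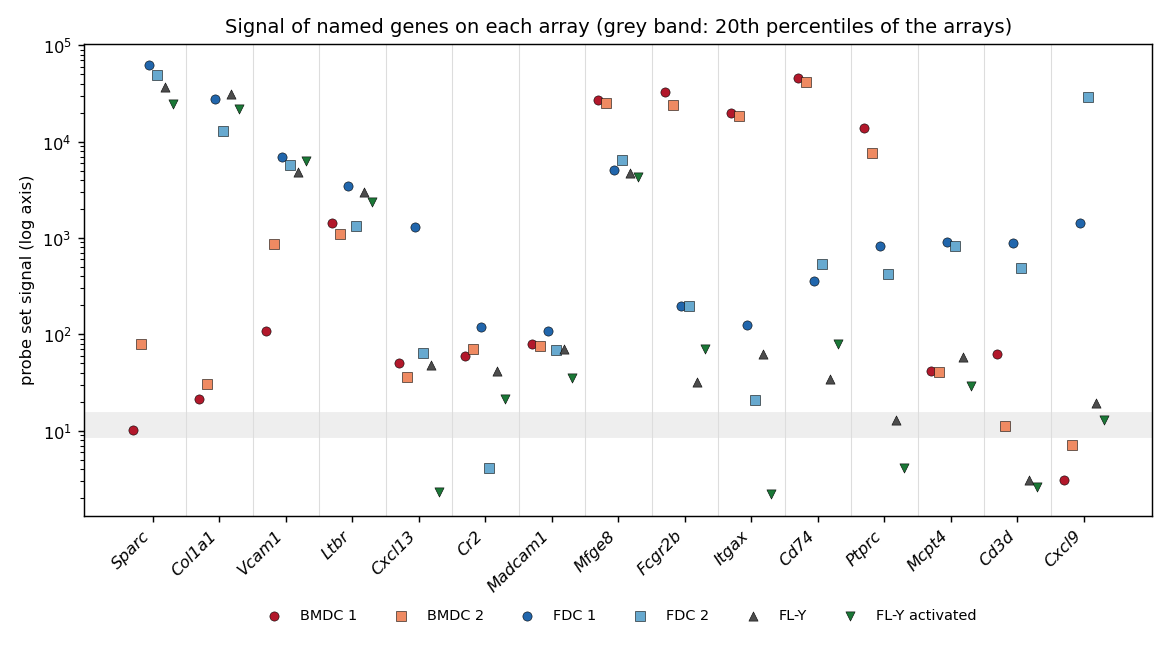
Signal of 15 genes on each of the 6 arrays, on a log axis, with the range of the arrays' 20th percentiles (8.7 to 15.4) as a grey band. Sparc and Col1a1 are high on the FDC and FL-Y arrays, Itgax and Cd74 on the BMDC arrays, and Cxcl13 and Cxcl9 differ between the 2 FDC arrays.

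Secreted immune factors moved both ways. Among 16 complement genes 7 rose and 5 fell (8 and 6 adjusted over the list alone): the inhibitor Serping1 rose by 8.85 ± 1.11 (SE), C2 by 7.74 ± 0.49 and C1s1 by 7.45 ± 0.41, while properdin, Cfp, fell by 7.38 ± 0.41. The complement list had a median of 2.65 and an adjusted p of 0.184. Of 25 chemokines 6 rose and 7 fell (10 and 10 adjusted over the list alone), with Cxcl9 at 8.40 ± 1.38 and Ccl11 at 7.10 ± 1.16 against Ccl17 at -7.26 ± 1.10 and Ppbp at -6.80 ± 0.77. The chemokine list had an adjusted p of 0.890, with a median of 0.32, a mean of 0.43 and the direction down in fry (adjusted p = 0.197). Cxcl9 and Ccl11 rested on unequal arrays, with signals of 1421 and 29344 for Cxcl9 and 20007 and 1625 for Ccl11 on FDC arrays 1 and 2, and both lost their call without either BMDC array. Their adjusted p was then 0.0670 and 0.0630 for Cxcl9 and 0.0621 and 0.0704 for Ccl11. Ccl17 lost its call without FDC array 1 (adjusted p = 0.0594). Of 26 interleukins and growth factors 6 rose and 2 fell (11 and 3 adjusted over the list alone), including the rises of Fgf7 (8.88), Kitl (5.82) and Vegfc (5.46) and the fall of Il1rn (-6.15). That list had an adjusted p of 0.0132, and adjusted p = 0.322 with an estimated correlation.

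Fc receptors and Toll-like receptor genes were read beside antigen presentation. Of 9 Fc receptors 4 fell and 0 rose (6 and 0 adjusted over the list alone), with Fcer1g at -7.20 ± 0.40 (SE), Fcgr3 at -6.87 ± 0.60 and Fcrls at -5.95 ± 0.51; the list had an adjusted p of 0.00162, and adjusted p = 0.217 with an estimated correlation. Of 19 genes of Toll-like receptor signalling 5 fell and 1 rose (11 and 1 adjusted over the list alone), with Ly86 at -6.15, Tlr8 at -4.98, Tlr7 at -4.79 and Tlr13 at -4.52. Its adjusted p was 1.90e-04, and adjusted p = 0.322 with an estimated correlation. Of 10 costimulation genes 3 fell and 0 rose (6 and 0 adjusted over the list alone): Cd48 (-5.81), Pdcd1lg2 (-5.22) and Cd86 (-4.44), the last of which lost its call without BMDC array 2 (adjusted p = 0.0569) or FDC array 1 (0.0828). This list had an adjusted p of 0.00124, and adjusted p = 0.499 with an estimated correlation. With limma 0 of 14 genes of MHC class I presentation were called (0 adjusted over the list alone, 0 at an unadjusted p under 0.05), and Nlrc5 and Tap1 had differences of 1.45 ± 1.03 and 0.95 ± 0.54. The class I list had a median of 0.18 (-0.33 and 0.62 within the array pairs) and an adjusted p of 0.438, and was called higher without FDC array 1 (adjusted p = 0.0172). Of 26 integrins and adhesion molecules 5 rose and 6 fell (9 and 8 adjusted over the list alone), with Cdh11 at 7.33 and Itgb2 at -6.27 and an adjusted p of 0.890 for the list. Of 27 genes of the lymphotoxin and NF-kB list 2 rose and 3 fell (7 and 5 adjusted over the list alone): Cxcl1 (3.58) and Il6 rose, and Traf1 (-3.06), Rel (-2.97) and Nfkbie (-2.65) fell, with an adjusted p of 0.884 for the list, a median of 0.12, a mean of 0.78 and the direction down in fry (adjusted p = 0.789). Without 1 array Traf1 and Rel lost their call in 2 cases each (BMDC array 2, adjusted p = 0.0942 and 0.0689; FDC array 1, 0.0835 and 0.0525), and Nfkbie in 3, without either BMDC array (0.0712 and 0.0725) or FDC array 1 (0.0566).

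Markers of other cell types were read on the same arrays. Of 16 granulocyte and mast cell markers 9 fell and 3 rose (9 and 3 adjusted over the list alone). The falls included the granulocyte genes S100a8 (-6.94), Ngp (-6.77; adjusted p = 0.0506 without FDC array 1) and Mpo (-6.73). The 3 that rose, named after their values were seen, were the mast cell proteases Tpsab1, Mcpt4 and Tpsb2, with signals of 1651, 909 and 1082 on FDC array 1 and 1253, 823 and 1036 on FDC array 2. The list had an adjusted p of 0.00451, and adjusted p = 0.220 with an estimated correlation. Of 11 T and NK cell markers 3 rose and 1 fell (4 and 1 adjusted over the list alone): the T cell receptor chains Cd3d (3.95 ± 0.66) and Cd3g (3.31 ± 0.58) and the co-receptor Cd8b1 (3.14 ± 0.42) rose, and Il7r fell by 4.31 ± 0.64 (SE). Cd3d and Cd3g lost their call without BMDC array 2 (differences of 3.15 and 2.69) or FDC array 1 (3.52 and 2.92). Cd8b1 lost it without BMDC array 2 (2.98) and Il7r without FDC array 1 (-3.82). Without either FDC array Cd8b1 fell below the filter and was not tested. The list had an adjusted p of 0.0185, and adjusted p = 0.605 with an estimated correlation; it lost its call without BMDC array 2 (adjusted p = 0.253) and without FDC array 1 (adjusted p = 0.317). Of 11 B cell markers 1 rose, the transcription factor Ebf1 (3.94 ± 0.78), and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.0743 for the list). Ebf1 lost its call without BMDC array 1 (adjusted p = 0.0592), BMDC array 2 (0.129) or FDC array 1 (0.0806), and the B cell list was called lower without BMDC array 2 (0.00357). Of 11 endothelial markers Vwf (-6.83) and Pecam1 (-4.29) fell, 2 also adjusted over the list alone, and of 6 epithelial markers Cdh1 (-4.52) fell, with 1 rise and 1 fall adjusted over the list alone. These lists had an adjusted p of 0.388 and 0.438.

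Interferon and cell cycle genes differed between the 2 FDC arrays as well as between the cell types. Of 19 type I interferon response genes Ifit3 (4.98 ± 0.72) and Ifit1 (3.75 ± 0.44) rose and Mx1 fell by 2.89 ± 0.52 (4 rose and 1 fell adjusted over the list alone). Ifit3 lost its call without either BMDC array (adjusted p = 0.0530 and 0.0531), and Mx1 without BMDC array 2 (0.101), FDC array 1 (0.0944) or FDC array 2 (0.0643). The list had a median of 1.13 (0.25 and 2.29 within the array pairs) and an adjusted p of 0.0111, and adjusted p = 0.624 with an estimated correlation. Its median on FDC array 2 lay 1.84 above that on FDC array 1, and without FDC array 2 its adjusted p was 0.305. Of 35 cell cycle genes 5 fell and 0 rose (18 and 0 adjusted over the list alone), with the proliferation marker Mki67 at -3.46 ± 0.51 and the replication factors Mcm6 at -2.93 ± 0.54, Mcm5 at -2.86 ± 0.57 and Cdt1 at -2.75 ± 0.56. Without BMDC array 1 or 2 these 4 genes lost their call, with an adjusted p of 0.0645 and 0.0599 for Mki67, 0.107 and 0.105 for Mcm6, 0.125 and 0.128 for Mcm5 and 0.132 and 0.133 for Cdt1; without FDC array 1 it was 0.0682 for Mcm6, 0.0790 for Mcm5 and 0.0859 for Cdt1. The list had a median of -2.11 (-2.48 and -1.30 within the pairs) and an adjusted p of 2.66e-09, and adjusted p = 0.499 with an estimated correlation. The median difference of its genes, FDC array 2 minus FDC array 1, was 1.39. Of 19 p53 target genes Phlda3 (2.56 ± 0.43) and Zmat3 (2.25 ± 0.44) rose and 0 fell (3 and 0 adjusted over the list alone). Both lost their call whichever array was left out, with an adjusted p of 0.0562 to 0.110 for Phlda3 and 0.0570 to 0.155 for Zmat3. That list had an adjusted p of 0.0185 and adjusted p = 0.273 with an estimated correlation, and without FDC array 2 its adjusted p was 0.0548. Of 11 housekeeping genes 0 passed the threshold with limma (0 rose and 2 fell adjusted over the list alone and at an unadjusted p under 0.05), with an adjusted p of 0.0644 for Tfrc, 0.0553 for Gusb and 0.0959 for the list.

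With camera 8 of the 27 lists were called higher and 9 lower, while fry called 12. With an estimated correlation camera called 0 (4 higher and 4 lower at an unadjusted p under 0.05). That version uses the 2 residual degrees of freedom. For hematopoietic signalling the estimate was 0.0139, near the preset 0.01, yet the adjusted p went from 3.39e-18 to 0.127. The estimate lay below the preset for fibroblast and mural cell markers (-0.0032), class II (-0.037), matrix proteases (-0.038) and TGF-beta (-0.020). It was also lower for the granulocyte (-0.038), Fc receptor (-0.074) and p53 lists (-0.055). Correlation therefore cannot account for the lost calls of these lists. For cell cycle (0.689), T and NK cell markers (0.710), type I interferon (0.730) and costimulation (0.569) the estimate was far above the preset. For these and the remaining called lists the loss cannot tell correlation from the small number of arrays. The number of calls fell to between 1312 and 2090 when 1 array was left out: 1333 without BMDC array 1, 1312 without BMDC array 2, 1652 without FDC array 1 and 2090 without FDC array 2. With the technical batch as a block, 2392 probe sets were called, 2038 of them among the 2413. Among named genes Il6 (adjusted p = 0.0648), Zmat3 (0.0630), Cdt1 (0.0539) and Mcm5 (0.0511) lost their call under the block, and Ccn5 (0.0364), Flrt3 (0.0167) and Gusb (0.0384) gained one.

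FL-Y was set against both cell types, with 1 array per state and no test. FL-Y lay on the side of FDC, beyond the midpoint between the FDC and BMDC means, for 1984 of the 2413 called probe sets (82.2%). The share was 76.4% for probe sets higher in FDC and 89.1% for those lower in FDC. For a probe set lower in FDC, any low FL-Y signal lies on the FDC side. The 89.1%, and in part the pooled 82.2%, therefore cannot tell likeness to FDC from a lack of BMDC transcripts. The activated line lay on that side for 79.7%. An FDC array left out of the fit lay there for 89.3% or 82.3% of the calls of the other 3 arrays, and a BMDC array for 6.68% or 6.86%. On the same calls FL-Y was lower than the FDC array both times, 83.5% beside 89.3% without FDC array 1 and 72.7% beside 82.3% without FDC array 2. Across 27022 probe sets the log2 values of FL-Y correlated with the FDC mean at r = 0.857 and with the BMDC mean at 0.693, and those of activated FL-Y at 0.849 and 0.695.

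FL-Y was near cultured FDC in the medians of some gene lists, matrix genes among them, and further from it in others. The fibroblast and mural cell markers had a median FL-Y minus FDC difference of -0.025 (percentile 43.9 among random lists), with 5 of 20 genes higher and 5 lower by at least 1. Housekeeping genes had a median of -0.024 (percentile 22.05). The collagen and matrix list had a median FL-Y minus FDC difference of -0.15 (percentile 11.6 among random lists), with 2 of 27 genes higher and 6 lower by at least 1, and activated FL-Y a median of -0.49 (percentile 0.87), with 1 higher and 9 lower. Dcn had a signal of 4233 in FL-Y and 49871 ± 3379 (SD, n = 2) in FDC, while Col1a1 had a signal of 31443 in FL-Y and 20257 ± 10565 (SD, n = 2) in FDC. The FDC markers had a median of -0.71 (percentile 0.93), with 1 of 18 genes higher and 8 lower by at least 1, and activated FL-Y a median of -1.17 (percentile 0.12), with 0 higher and 12 lower. Cell cycle genes had a median of 2.79 above FDC (percentile 100), with 33 of 35 higher by at least 1; Mki67 had a signal of 6051 in FL-Y against 379 and 854 in FDC. In activated FL-Y the cell cycle median was 2.92. The p53 target genes had a median of -1.47 (percentile 0.01), with 12 of 19 lower by at least 1, and -1.15 in activated FL-Y; SV40 large T antigen is known to bind p53. FL-Y also stood below FDC for the medians of type I interferon response (-4.12), chemokines (-2.68), MHC class I presentation (-2.43), interleukins and growth factors (-2.14), hematopoietic signalling (-1.93), complement (-1.34) and matrix proteases and inhibitors (-1.31), each at percentile 0.02 or below. The same held for T and NK cell markers (-2.90), Fc receptors (-2.19) and granulocyte and mast cell markers (-1.58). Rarres2 was at 271 in FL-Y and 57922 ± 11371 (SD, n = 2) in FDC, and Iigp1 at 30.4 and 36375 ± 17070.

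Activation of FL-Y through the lymphotoxin beta receptor was read as the difference between 2 single arrays, with no replicate check. Targets of lymphotoxin and NF-kB signalling were higher on the activated array: the list's median difference was 0.95 (percentile 100 of random lists), with 13 of 26 genes higher by at least 1 and 1 lower by at least 1. Cxcl10, a chemokine for T cells, differed by 3.37 with signals of 106 and 1232, the adhesion molecule Icam1 by 2.64, the apoptosis inhibitor Birc3 by 2.43, Traf1 by 2.24, Cxcl1 by 2.20 and Nfkbie, an inhibitor of NF-kB, by 1.97. Chemokines had a median of 0.75 (percentile 100), with 10 of 24 higher by at least 1, and genes of MHC class I presentation a median of 0.45 (percentile 100). Cell cycle genes had a median of 0.24 (percentile 100) and housekeeping genes of -0.21 (percentile 9.85). Between the 2 untreated FDC arrays the median differences of class I and cell cycle genes were larger, 0.97 and 1.39 (both percentile 100). Those of the lymphotoxin list and the chemokines were -0.11 (percentile 28.7) and 0.22 (percentile 93.4). The collagen and matrix list had a median of -0.47 (percentile 0), beside a median of -0.31 over the brightest 1% of the probe sets above the filter. Under quantile normalization the collagen and matrix median was -0.29 and the housekeeping median -0.022.

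The largest differences towards the activated array were those of the gelatinase Mmp9 (4.23), Flrt3 (4.20), the phosphatase Ptpn22 (3.68), Slco4a1 (3.48), Cxcl10 (3.37), Stmn2 (3.14), the chemokine Cxcl16 (3.09), Hand2 (3.04), Slamf8 (2.99) and U90926 (2.99). The largest in the other direction were those of Sfrp2 (-4.02), a secreted Wnt modulator, Ccn5 (-3.57), Sned1 (-3.17), Gkn2 (-3.05), Rasl11a (-2.87), Nwd1 (-2.86), Prss2 (-2.85), Pappa (-2.84), Cyp4a31 (-2.81) and Shisa7 (-2.81). The lower signal lay under the array's 20th percentile for Flrt3 (7.4), Stmn2 (7.2) and Slamf8 (2.0) on the FL-Y array and for Sned1 (8.3), Gkn2 (8.2), Prss2 (3.8), Cyp4a31 (2.3) and Shisa7 (2.9) on the activated one, so the size and rank of these 8 differences depend on the offset. Over the 27022 probe sets above the filter 65 were higher and 136 lower by at least 2 on the activated array, and 2394 differed by at least 1; without the filter 91 were higher and 405 lower by at least 2. Differences of at least 1 numbered 5461 between the BMDC arrays and 6457 between the FDC arrays. The activation counts were thus below those between paired arrays of one cell type. Those pairs span the technical batches read from the control probe sets, while the FL-Y arrays had similar control ratios (0.0628 and 0.0723). The counts are therefore not like for like. Under quantile normalization 154 probe sets were higher and 134 lower by at least 2, and with an offset at the 40th percentile 27 were higher and 9 lower.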

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

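The test of row order in this part was chosen only after the control values had been seen. A control probe set outside the comparisons, AFFX-MURINE_b1_at, had a signal of 34959.4 on the FL-Y array and 22941.4 on the activated FL-Y array, while its highest signal on the 4 FDC and BMDC arrays was 657.2. It is 1 of 3 control probe sets for mouse repeat sequence, and another of them, AFFX-MUR_b2_at, went the other way, with 841 and 798 on the FL-Y arrays and 44770 to 51121 on the other 4.

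A candidate explanation is that 3 rows were in another sort order when the FL-Y values were joined to the table. AFFX-MUR_b2_at, AFFX-MURINE_b1_at and AFFX-MURINE_B2_at are the only 3 rows that move between the sort orders compared. Both orders ignore capital letters and differ in whether the character _ comes before or after letters. An order that reads capital letters apart was not tested. After the values of these rows were rotated on the FL-Y arrays, the largest log2 difference from the FDC mean was 1.18, against 6.56 before. This could have failed, since the rotated values did not have to lie near those of FDC, but the test was built on the values it explains. A real difference in repeat transcripts between the line and the primary cells was not tested and stays open. No gene named in the report is read from these rows.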

How the results depend on the processing

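The technical batch block was chosen only after the control probe sets had been seen; the other settings were planned. No paired analysis was possible because of the labels, which share only the number 2 between the cell types and give the first BMDC array no number; the batch block, read from control probe sets, treats the first arrays and the second arrays as pairs.

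The 2413 calls became 2448 under quantile normalization (2373 shared), 2520 after rescaling to one median (2388 shared), 3119 with the higher offset, 2419 with the stricter filter, 3083 with trend and robust settings and 2392 with the technical batch block (2038 shared). With no offset 1443 were called (787 higher, 656 lower), 1441 of them shared. With no filter 1433 were called (795 higher, 638 lower), where 45037 probe sets were adjusted for. With the FL-Y arrays as another group, which adds residual degrees of freedom, 3777 were called (1980 higher, 1797 lower). That group pooled the untreated and the activated array as if they were replicates. Their log2 differences had an SD of 0.585, against 0.872 between the BMDC arrays and 0.996 between the FDC arrays. With a gene's probe sets averaged, 821 genes were higher among 10916 tested. At an adjusted p under 0.01, 775 were called (417 higher, 358 lower). Leaving out 1 array, with the lone array assumed to vary like the other group, gave 1312 to 2090 calls, 776 to 1042 higher and 536 to 1048 lower. With an estimated correlation, where camera uses the 2 residual degrees of freedom, 0 lists were called, 0 higher and 0 lower. The 17 called lists became 16 with no offset and 16 with averaged probe sets, T and NK cell markers losing their call (adjusted p = 0.0608 and 0.150), and 18 with no filter, where B cell markers were called lower (0.0398).

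List means changed sign, or the test's direction turned, for chemokines (0.074 with averaged probe sets, 0.11 to 0.71 without 1 array), integrins and adhesion molecules (-0.97 to -0.42 without 1 array, -0.50 with the technical batch block) and MHC class I presentation (-0.21 to 0.77 without 1 array); the cause was not tested. Among genes the range without 1 array crossed 0 for Cyp4a31 (-0.19 to 1.24), Icam1 (-0.75 to 0.23), Cxcl16 (-0.60 to 0.0034), Madcam1 (-0.14 to 0.40), Prss2 (-0.038 to 1.30), Ptpn22 (-1.71 to 0.59), Slco4a1 (-3.31 to 1.45), Gkn2 (-1.71 to 0.58) and Nlrc5 (-0.068 to 2.96). Cr2 had 0.76 without FDC array 2. None of these genes was called with all 4 arrays. Of the values of named genes across settings, 1661 kept their direction and side of the threshold, 121 were no longer called, 31 were newly called and 10 changed direction.

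FL-Y lay on the FDC side for 82.2% of calls: 86.8% with no offset (activated 85.7%), 77.5% with the higher offset (74.99%), 87.1% with no filter (85.7%) and 72.7% to 88.7% without 1 array (69.7% to 86.4%). Its r with the FDC mean was 0.837 with no offset, 0.900 with no filter (0.901) and 0.824 to 0.855 without 1 array (0.809 to 0.848). Its r with the BMDC mean was 0.688 under quantile normalization, 0.656 with no offset (0.656), 0.725 with the higher offset (0.727), 0.811 with no filter (0.818) and 0.687 to 0.690 without 1 array (0.688 to 0.692). A filter that keeps dim probe sets and an offset that shrinks them act on these values by construction; the cause of the other shifts was not tested. The cell cycle median of FL-Y above FDC stayed between 2.07 and 3.55, and the p53 median between -1.67 and -1.33.

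For activation, quantile normalization gave 154 rises of at least 2 and medians of -0.29 for collagens and -0.022 for housekeeping genes. No offset gave 3770 differences of at least 1 and 1053 of at least 2 (375 rises, 678 falls), the higher offset 668 and 36 (27 rises, 9 falls), and no filter 7029 and 496 (405 falls). The offset limits what dim genes can show: signals near the 20th percentiles of 8.7 to 15.4 carry little information.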

Other observations

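The gene lists in this part were written after the deposited values were first seen, and the genes named here were chosen after their values were seen; the comparisons of the 2 FDC arrays were chosen after their interferon genes had been seen to differ. Transcription factors of neural crest and skeletal development stood higher in FDC than in BMDC: 9 of 21 rose and 0 fell (16 and 0 adjusted over the list alone). Osr1 was higher by 5.27 ± 0.44 (SE), Ebf2 by 5.18 ± 0.46, Nr2f2 by 4.81, Tbx15 by 4.29, Ebf3 by 3.37, and the Hox genes Hoxc9 by 3.79, Hoxc6 by 3.26 and Hoxc8 by 2.74; Prrx2 was the remaining rise. The list had an adjusted p of 3.00e-07, and adjusted p = 0.211 with an estimated correlation, and a median of 2.85 and 2.92 within the array pairs.

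Genes of the interferon-gamma response stood higher in FDC, 4 of 19 rising and 0 falling (7 and 0 adjusted over the list alone): the GTPases Gbp6 (6.33), Irgm2 (4.33), Igtp (4.13) and Irgm1 (3.84). The list had an adjusted p of 0.00314, and adjusted p = 0.774 with an estimated correlation, with a median of 0.72 between the first arrays and 2.75 between the second. Of 22 lysosome genes 3 fell and 0 rose (9 and 0 adjusted over the list alone), among them the proton pump subunit Atp6v0d2 (-6.49) and the protease Ctsc (-5.32); its adjusted p was 7.52e-04, and adjusted p = 0.774 with an estimated correlation. Of 21 genes of glycolysis and hypoxia Adm (6.92) and P4ha2 (5.89) rose and Car9 (-2.09) fell (2 and 1 adjusted over the list alone), and the list's median (-0.22) and mean (0.49) differed in sign (adjusted p = 0.683). With limma 0 of 17 genes of cholesterol synthesis were called (2 higher and 3 lower at an unadjusted p under 0.05; 0 adjusted over the list alone; adjusted p = 0.476). The same held for 0 of 10 genes of unrelated tissues (0 at an unadjusted p under 0.05; 0 adjusted over the list alone; adjusted p = 0.683). Of 11 genes in another mast cell list 1 rose and 1 fell (2 and 2 adjusted over the list alone; adjusted p = 0.683), with a median of -0.84 and a mean of 0.25, and of 17 genes in another T cell list 1 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.359).

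Leukocyte transcripts were above FL-Y on the FDC arrays. For 24 hematopoietic signalling genes the signal was taken as a share of the BMDC mean, without the offset. The median share was 5.27% and 4.08% on FDC arrays 1 and 2, against 0.254% on the FL-Y array and 0.397% on the activated one. With the offset the median log2 difference of FL-Y from BMDC was -7.20. The size of the FL-Y shares thus depends on how background is treated. Higher background on the FDC arrays than on the unactivated FL-Y array was tested with genes of unrelated tissues. Of 33 measured, the 12 above the filter had a median FDC minus FL-Y difference of -0.080 (95% bootstrap interval -0.51 to 0.11). The signalling genes had 1.93, and the upper limit of 0.11 was under the bound of 0.64 set for it. The filter had removed the dimmer genes of unrelated tissues, where background weighs most, so the test cannot exclude higher background. The 20th percentile was 14.7 and 14.8 on the FDC arrays and 12.1 on the FL-Y array. Activated minus FDC, the medians of the unrelated and the signalling genes were -0.79 and -2.56, so background is not excluded there either. Residual T cells were tested as a source with 15 genes of another T cell list. Their median was 1.82 above FL-Y (0.46 to 2.81), 13 of them higher, with 1.94 and 1.68 from FDC arrays 1 and 2 alone. Residual mast cells were tested with 10 genes of another mast cell list. Their median was 1.36 (0.55 to 3.41), 9 of them higher. Both medians were above the bound of 1 set for them. The mast cell median was only 0.56 from FDC array 1 alone, under that bound, and 1.09 from FDC array 2. FL-Y minus BMDC had medians of -1.92 and -1.42 on the T cell and mast cell genes, so BMDC stood above FL-Y by similar amounts. These gaps are therefore not particular to FDC and cannot tell residual cells from low values in FL-Y. Expression of these genes by FDC themselves was not tested and stays open.

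Interferon response genes were higher on FDC array 2 than on FDC array 1. The median difference was 1.81 (1.27 to 2.68, over genes) over the interferon-gamma list, 18 of 19 genes higher. The estimated correlation between the genes of this list was 0.650, and each side of the difference is a single array. Scaling of the arrays was argued against, since the median was 1.87 (1.28 to 2.78) under quantile normalization. A technical batch shared with BMDC array 2 cannot be told apart from other causes by the bound set for it: the BMDC difference had a median of -0.0076, but its upper limit of 0.56 was above 0.5. A difference between the 2 FDC cultures, such as cytokine from other cells in the dish, could also be the cause, and no test was made of it.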
